A study of Mus musculus with 36 samples.

How the data were processed

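RNA sequencing measured gene expression in 36 libraries of mouse cells in 12 groups of 3. The groups were 4 cell populations, each after phosphate-buffered saline (PBS), OMV-SIRP or OMV-SIRP-G. The populations were granulocyte-macrophage progenitors (GMP) and monocytes, both from bone marrow, and tumour-associated macrophages (TAM) from mice bearing B16-F10 melanoma or MC38 colon carcinoma. Group and replicate were taken from the sample labels. Per the labels' protocols, RNA was taken up in TRIzol and made into messenger RNA libraries with a NEBNext kit. The design text speaks of 3 samples of each group being pooled, which can be read as pools sequenced as 1 library or as 3 libraries kept per group. Nothing says that the 3 libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

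The authors deposited FPKM (fragments per kilobase of gene length, divided by sequencing depth) in 3 tables, 1 for GMP and monocytes and 1 for each tumour model, of 56026, 56575 and 57252 gene models. Of these models, 453, 1002 and 1679 carried no Ensembl identifier, and 21900 in each table were protein coding. Per the submitters' processing notes, the genome build was GRCm38 and the tools included HISAT2 2.0.5, StringTie and featureCounts 1.5.0-p3; their roles and settings are not given in the sources used here. Positions are those of the deposited tables. Multiplying each FPKM by its gene length gave whole multiples of 1 read in 100% of values, at a tolerance of 0.05 reads, so each library's depth could be recovered. The libraries held between 13036567 and 19822660 reads assigned to genes. The recovered reads also showed that the deposited FPKM already carried a median-of-ratios scaling between libraries of the same table. The 3 tables were scaled separately, so no test was made across tables.

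Expression was compared on log2(FPKM + 1) with limma 3.58.1 (statmod 1.5.0, R 4.3.3), using lmFit and eBayes with trend and robust set. Each population was fitted with all of its 9 libraries, so that its 3 groups shared an estimate of the spread. Genes with an FPKM of at least 1 in at least 3 libraries of the population were tested. P-values were adjusted by Benjamini-Hochberg within each comparison, at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. The comparisons, 3 per population, were each treatment with PBS and OMV-SIRP-G with OMV-SIRP. GMP and monocytes shared a table, so the difference between their responses was also tested, as an interaction in a fit of all 18 libraries. Log2 changes are given with their standard error and FPKM as mean ± SD, n = 3 libraries.

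A set of 32 gene lists covered macrophage states, signalling and metabolic pathways, blood lineages, cell types that the samples could also hold, and RNA quality. Lists with at least 5 measured members were tested with camera of limma, with an estimated correlation between genes, which asks whether a list moved relative to the other genes. Camera adjusted p-values are Benjamini-Hochberg values over the lists of a comparison. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Genes were named by a rule. In each comparison with PBS the 10 largest and the 10 smallest log2 changes were taken among protein-coding genes past the threshold that had a mean FPKM of at least 5 and groups that did not overlap. In the other comparisons 5 of each were taken, without the overlap criterion for the interactions. Up to 4 members of each list with the lowest adjusted p were added, and Sirpa, Cd47, Arg1, Nos2, Mrc1 and Cd86 were followed in every population. Of the genes so named, 1 is not reported here. The tests, the lists, the naming rule and the first alternative settings below were fixed before the data were examined.

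These settings were another pseudocount, no filter on low values, another scaling between libraries, a fold-change minimum, a fit of the 2 compared groups alone, replicate number as a block, a camera correlation preset to 0.01, the fry test, and leaving out each library in turn. Scaling to total reads, limma voom on the recovered reads, and leaving out 2 MC38 TAM libraries together were added after the data were seen. The code was tested on simulated data with 200 genes changed by known amounts in each comparison. For OMV-SIRP against PBS, the limma test recovered 92.3% of genes changed by 1 on the log2 scale in GMP, 67% in monocytes, 29.5% in B16 TAM and 10.2% in MC38 TAM. At a change of 2 it recovered 96.9%, 98.1%, 86.7% and 66.3%. The tumour comparisons, MC38 above all, were thus the least able to show small changes. The share of false calls among those made was 8.25%, 2.34%, 5.56% and 2.7% at the threshold of 0.05, and reached 7.64% for OMV-SIRP-G against PBS in B16 TAM. The list test, simulated for OMV-SIRP against PBS in GMP and B16 TAM only, called the 1 list that was shifted and 0 of the others. Data were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Reads from near-identical gene copies, such as the haemoglobin genes and the Ear ribonucleases, can be divided arbitrarily between the copies. Kit strandedness and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes could share reads.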

Results

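The series asked how an engineered outer membrane vesicle (OMV), a particle derived from the outer membrane of bacteria, changed macrophages and the bone marrow cells that give rise to them. RNA was sequenced from granulocyte-macrophage progenitors (GMP) and monocytes of the bone marrow, and from tumour-associated macrophages (TAM) of mice bearing B16-F10 melanoma or MC38 colon carcinoma. Each population was measured after phosphate-buffered saline (PBS), OMV-SIRP or OMV-SIRP-G, names that the labels do not spell out further, with 3 libraries per group and 36 in all. The libraries held 13036567 to 19822660 reads assigned to genes. Log2(FPKM + 1) values of replicates correlated across genes at 0.98 to 0.989 in GMP, 0.925 to 0.988 in monocytes, 0.929 to 0.976 in B16 TAM and 0.81 to 0.95 in MC38 TAM. Genes said to rise or fall had a limma adjusted p under 0.05. Values are FPKM as mean ± SD, values in brackets after a gene are log2 changes ± SE, and list counts are of measured members, with the median of their log2 changes.

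In GMP, OMV-SIRP raised several genes of maturing neutrophils and lowered eosinophil ribonuclease, haemoglobin and interferon response genes. Retnlg (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496) encodes a resistin-like protein of neutrophils, and its FPKM rose from 82.4 ± 16.5 to 472 ± 3.74 FPKM (log2 change 2.52 ± 0.13, adjusted p = 3.76e-06). The neutrophil collagenase Mmp8 rose from 32.7 ± 1.73 to 111 ± 5.77 FPKM (log2 change 1.73 ± 0.06, adjusted p = 6.06e-07), and the gelatinase Mmp9 from 49.1 ± 4.73 to 131 ± 6.0 FPKM (log2 change 1.40 ± 0.07, adjusted p = 4.71e-06). Ly6g, the surface marker of mouse neutrophils, rose from 16.9 ± 1.59 to 53.4 ± 1.47 FPKM (log2 change 1.60 ± 0.06, adjusted p = 1.32e-06). Alox15, the 15-lipoxygenase of eosinophils and macrophages, fell from 78.1 ± 2.16 to 8.49 ± 0.802 FPKM (log2 change -3.06 ± 0.06, adjusted p = 2.62e-08). Serpinb2, an inhibitor of plasminogen activators, fell from 16 ± 1.34 to 2.86 ± 0.0491 FPKM (log2 change -2.14 ± 0.06, adjusted p = 2.67e-07). The eosinophil-associated ribonucleases Ear6 (-1.87 ± 0.09), Ear1 (-1.95 ± 0.12) and Ear2 (-1.97 ± 0.09) fell together with the related Gm8113 (-1.75 ± 0.12). The haemoglobin genes Hbb-bs (log2 change -3.21 ± 0.18, adjusted p = 1.24e-05) and Hba-a1 (-2.33 ± 0.25) fell as well. The Ear and the haemoglobin genes have near-identical copies, which makes the split of reads between the copies uncertain. Other genes among the 10 largest rises were Ceacam10 (1.76 ± 0.07), the osteopontin gene Spp1 from 7.92 ± 0.895 to 27.2 ± 0.336 FPKM, the formyl peptide receptor Fpr1 from 4.60 ± 0.305 to 15.6 ± 1.87 FPKM, S100a6 from 76.5 ± 13.3 to 224 ± 20.8 FPKM, Acvrl1 (1.35 ± 0.09) and Plbd1 from 39.3 ± 1.93 to 94.1 ± 1.30 FPKM. The growth factor gene Csf1 fell from 15.4 ± 2.24 to 5.45 ± 0.304 FPKM (log2 change -1.34 ± 0.09, adjusted p = 1.63e-05), and Ms4a4a fell too (-1.20 ± 0.13). Arg1, which encodes arginase, rose from 0.175 ± 0.0691 to 3.35 ± 0.663 FPKM (log2 change 1.88 ± 0.11, adjusted p = 8.69e-06), and Nos2, the inducible nitric oxide synthase, from 0.544 ± 0.0701 to 2.28 ± 0.109 FPKM (log2 change 1.09 ± 0.08, adjusted p = 3.23e-05), both at low FPKM. Sirpa fell (log2 change -0.20 ± 0.05, adjusted p = 0.0243), lost without PBS 2, PBS 3, OMV-SIRP 1 or OMV-SIRP 3 (adjusted p up to 0.0898).

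The interferon-stimulated list was lower in these GMP, where 16 of 18 members fell (16 adjusted over the list alone, median -0.65, camera adjusted p = 0.00401). Among them, Oas2 fell from 10.8 ± 1.37 to 4.75 ± 0.604 FPKM and Irf7 from 7.90 ± 0.191 to 4.44 ± 0.483 FPKM. In the hypoxia and angiogenesis list 9 of 11 members rose (9 adjusted over the list alone, median 0.67, camera adjusted p = 0.0241), but the list call was lost without PBS 2, PBS 3 or OMV-SIRP 2 (adjusted p up to 0.0679). In the erythroid list 4 of 5 members fell (5 adjusted over the list alone, median -1.62, camera adjusted p = 0.0412), and that call was lost without OMV-SIRP 1, 2 or 3 (adjusted p up to 0.0823), and without a PBS library fewer than 5 members were measured. Most members of several other lists moved one way without the list passing camera. In the neutrophil maturation list 12 of 14 members rose (12 adjusted over the list alone, median 0.76, camera adjusted p = 0.0897 with an estimated correlation). In the glycolysis list 12 of 14 members rose (12 adjusted over the list alone, median 0.53, camera adjusted p = 0.0897 with an estimated correlation), with Tpi1 rising from 244 ± 31.1 to 446 ± 7.22 FPKM and Pgk1 from 627 ± 41.6 to 921 ± 11 FPKM. In the cell cycle list 11 of 16 members rose (12 adjusted over the list alone, median 0.54, camera adjusted p = 0.0663 with an estimated correlation). In the mast cell and basophil list 7 of 8 members fell (7 adjusted over the list alone, median -0.85, camera adjusted p = 0.0621 with an estimated correlation). The transcription factor gene Gata2 of the stem and early progenitor list fell from 31.2 ± 2.60 to 18.4 ± 1.09 FPKM. In the B cell list 5 of 5 members fell (5 adjusted over the list alone, median -1.07, camera adjusted p = 0.107 with an estimated correlation). In all, 2232 of 12287 genes tested passed the threshold, 1308 higher and 924 lower, of which 55 and 59 changed by at least 2-fold. With FPKM scaled to total reads 821 genes were higher and 1825 lower, so the balance between rises and falls rested on the scaling. The count was 1390 without OMV-SIRP 2 and 1413 without OMV-SIRP 3.

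OMV-SIRP-G raised stress and macrophage genes of GMP, and lowered eosinophil ribonuclease and haemoglobin genes. Retnlg rose from 82.4 ± 16.5 to 714 ± 29.3 FPKM (log2 change 3.12 ± 0.13, adjusted p = 6.9e-07), Mmp8 from 32.7 ± 1.73 to 184 ± 4.67 FPKM (log2 change 2.46 ± 0.06, adjusted p = 3.53e-08) and Fpr1 from 4.60 ± 0.305 to 30.9 ± 3.78 FPKM. The heat-shock gene Hspa1b rose from 0.605 ± 0.0541 to 10.1 ± 1.05 FPKM (log2 change 2.79 ± 0.08, adjusted p = 9.99e-08), and the glycoprotein gene Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929) from 13.3 ± 0.229 to 78.8 ± 2.68 FPKM (log2 change 2.48 ± 0.05, adjusted p = 1.38e-08). The cathepsin gene Ctsk rose from 1.08 ± 0.146 to 10.1 ± 0.280 FPKM. Spp1 from 7.92 ± 0.895 to 43.0 ± 1.67 FPKM, the fatty acid-binding protein gene Fabp5 from 2.97 ± 0.0781 to 18.6 ± 1.44 FPKM, the cytokine gene Il1b from 2.61 ± 0.413 to 14.1 ± 1.97 FPKM and Stfa2 (2.41 ± 0.14) completed the 10 largest rises. Arg1 reached 0.175 ± 0.0691 to 8.10 ± 0.633 FPKM (log2 change 2.95 ± 0.11, adjusted p = 3.86e-07), and Nos2 rose as well (log2 change 1.47 ± 0.08, adjusted p = 4.62e-06). The platelet factor gene Pf4 rose from 15 ± 2.95 to 42.5 ± 2.95 FPKM. Hbb-bs fell from 27.2 ± 2.94 to 2.19 ± 0.828 FPKM and Hba-a1 fell with it (-2.30 ± 0.25). Ear6 from 431 ± 54.0 to 143 ± 1.78 FPKM, Ear2 (-1.53 ± 0.09), Ear1 (-1.37 ± 0.12) and Gm8113 (-1.35 ± 0.12) fell, with the same uncertainty between copies, and Alox15 fell from 78.1 ± 2.16 to 41.3 ± 1.56 FPKM. The interferon-inducible genes Ifi211 (-1.09 ± 0.11) and Ifi27l2a (-0.97 ± 0.14) and the lipolysis inhibitor gene G0s2 (-1.04 ± 0.11) also fell. Cd47 fell (log2 change -0.21 ± 0.04, adjusted p = 0.0151), a call lost without PBS 2, OMV-SIRP-G 2 or OMV-SIRP-G 3 (adjusted p up to 0.0681), while Sirpa, the receptor for Cd47, had a log2 change of -0.01 ± 0.05 and an adjusted p of 0.906. Mrc1 rose (log2 change 0.46 ± 0.10, adjusted p = 0.0208), lost without PBS 2 (adjusted p = 0.0646).

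Of the lists, 8 passed camera in this comparison. In the immediate-early and heat-shock stress list 13 of 14 members rose (14 adjusted over the list alone, median 0.68, camera adjusted p = 0.0133). In the interferon-stimulated list 11 of 18 members fell and 2 rose (14 and 2 adjusted over the list alone, median -0.39, camera adjusted p = 0.0133). In the cholesterol synthesis list 12 of 15 members fell (13 adjusted over the list alone, median -0.28, camera adjusted p = 0.0133), with Hmgcs1 falling from 19.3 ± 0.546 to 14.5 ± 1.35 FPKM and Cyp51 from 17.3 ± 0.281 to 13.4 ± 0.317 FPKM. In the hypoxia and angiogenesis list 10 of 11 members rose (10 adjusted over the list alone, median 0.43, camera adjusted p = 0.0133). In the megakaryocyte and platelet list 5 of 7 members rose (6 adjusted over the list alone, median 0.59, camera adjusted p = 0.0133). In the macrophage identity list 7 of 11 members rose (8 and 2 adjusted over the list alone, median 0.57, camera adjusted p = 0.02), with the receptor gene Cd14 rising from 52.8 ± 3.63 to 79.0 ± 4.12 FPKM. In the lipid-associated TAM list 8 of 14 members rose (12 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 0.0377), a call lost without PBS 2, OMV-SIRP-G 1, OMV-SIRP-G 2 or OMV-SIRP-G 3 (adjusted p up to 0.0648). In the erythroid list 4 of 5 members fell (4 adjusted over the list alone, median -1.52, camera adjusted p = 0.0258), a call lost without OMV-SIRP-G 3 (adjusted p = 0.0591), and without a PBS library fewer than 5 members were measured. The MHC class II list did not pass, although 7 of 10 members rose (8 adjusted over the list alone, median 0.50, camera adjusted p = 0.0553 with an estimated correlation). The neutrophil maturation list did not pass either, and 6 of 14 members rose and 3 fell (6 and 4 adjusted over the list alone, median 0.13, camera adjusted p = 0.464 with an estimated correlation). A total of 1471 genes passed the threshold, 830 higher and 641 lower, of which 102 and 35 changed by at least 2-fold. The count was 919, 892 and 969 without OMV-SIRP-G 1, 2 and 3 in turn.

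Set directly against OMV-SIRP, OMV-SIRP-G left GMP with more macrophage and stress transcripts and fewer transcripts of most glycolysis and cell cycle genes. Alox15 was higher by 2.16 ± 0.06 on the log2 scale (adjusted p = 3.89e-07), and Serpinb2 rose from 2.86 ± 0.0491 to 15 ± 0.607 FPKM. The immediate-early gene Fosb rose from 6.80 ± 0.674 to 19.4 ± 0.760 FPKM, Gpnmb from 31.3 ± 1.51 to 78.8 ± 2.68 FPKM and Ms4a4a from 3.98 ± 0.290 to 11.6 ± 2.65 FPKM. Camp, which encodes the cathelicidin of neutrophil granules, fell from 3857 ± 361 to 1628 ± 52.3 FPKM, and so did Orm1 (-1.25 ± 0.18). The hypoxia-responsive genes Bnip3 from 98.6 ± 2.25 to 51.1 ± 0.435 FPKM and Fam162a from 78.6 ± 5.90 to 40.4 ± 3.04 FPKM fell, and the cytochrome oxidase subunit gene Cox4i2 fell from 9.74 ± 0.609 to 2.08 ± 0.348 FPKM. In the stress list 12 of 14 members rose (13 adjusted over the list alone, median 0.66, camera adjusted p = 0.0313). In the macrophage identity list 6 of 11 members rose and 1 fell (6 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 0.0313). In the monocyte lineage list 7 of 14 members rose (8 and 2 adjusted over the list alone, median 0.25, camera adjusted p = 0.0313), with the transcription factor Klf4 higher (1.01 ± 0.09). In the cell cycle list 13 of 16 members fell (14 adjusted over the list alone, median -0.47, camera adjusted p = 0.0313), with Top2a falling from 60.9 ± 1.90 to 41.4 ± 0.315 FPKM. In the cholesterol synthesis list 10 of 15 members fell (11 adjusted over the list alone, median -0.27, camera adjusted p = 0.0313). Calls that depended on single libraries were those of 3 lists. In the megakaryocyte and platelet list 5 of 7 members rose (5 adjusted over the list alone, median 0.49, camera adjusted p = 0.0343), lost without OMV-SIRP 2, OMV-SIRP 3 or OMV-SIRP-G 2 (adjusted p up to 0.0736). In the interferon-stimulated list 8 of 18 members rose (8 adjusted over the list alone, median 0.19, camera adjusted p = 0.039), lost without OMV-SIRP 1, OMV-SIRP 2 or OMV-SIRP-G 1 (adjusted p up to 0.0618). In the TLR and NF-kB response list 8 of 18 members rose and 2 fell (8 and 2 adjusted over the list alone, median 0.12, camera adjusted p = 0.0467), lost without OMV-SIRP 1, OMV-SIRP 2, OMV-SIRP 3, OMV-SIRP-G 1 or OMV-SIRP-G 2 (adjusted p up to 0.08). Glycolysis did not pass, although 12 of 14 members fell (13 adjusted over the list alone, median -0.57, camera adjusted p = 0.0509 with an estimated correlation), with Pgk1 falling from 921 ± 11 to 559 ± 5.01 FPKM and Tpi1 from 446 ± 7.22 to 242 ± 11.3 FPKM. In total 1821 genes passed, 823 higher and 998 lower. With total-read scaling 1344 were higher and 606 lower. The count was 1068 without OMV-SIRP 2, 1094 without OMV-SIRP 3, 1131 without OMV-SIRP-G 1 and 1159 without OMV-SIRP-G 2.

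**Figure D1:**
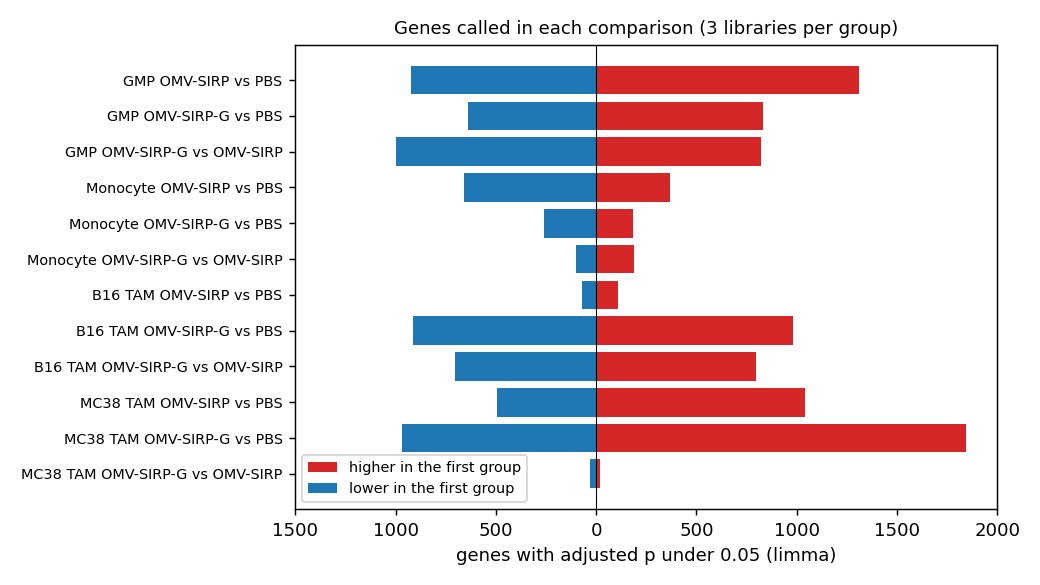
Number of genes with a limma adjusted p under 0.05 (horizontal) in each comparison (vertical), 3 libraries per group, with bars to the right for genes higher in the first group named and to the left for genes lower in it. The totals ran from 54 genes (MC38 TAM, OMV-SIRP-G against OMV-SIRP) to 2809 (MC38 TAM, OMV-SIRP-G against PBS).

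In bone marrow monocytes OMV-SIRP lowered interferon-stimulated genes and several inflammatory genes, and raised the MHC class II gene H2-Aa and the macrophage receptor genes Mrc1 and Mgl2. Mmp14 (ENSMUSG00000000957, chromosome 14, 54431612 to 54445364) encodes a membrane-bound matrix metalloproteinase, and it rose from 4.30 ± 1.07 to 21.1 ± 1.99 FPKM (log2 change 2.08 ± 0.16, adjusted p = 0.000381). The adhesion receptor gene Adgre4 rose from 1.98 ± 0.510 to 10.5 ± 0.0771 FPKM, H2-Aa from 2.48 ± 0.624 to 10.4 ± 0.993 FPKM, and Mrc1, the mannose receptor gene, from 0.898 ± 0.364 to 5.19 ± 0.512 FPKM (log2 change 1.72 ± 0.16, adjusted p = 0.000814). The lectin gene Mgl2 rose from 11.4 ± 1.77 to 32.2 ± 0.574 FPKM, Gpnmb from 29.0 ± 3.02 to 75.0 ± 1.29 FPKM, Stab1 from 2.54 ± 0.638 to 8.96 ± 0.174 FPKM and the immediate-early gene Fos from 205 ± 1.13 to 542 ± 40.7 FPKM. P2ry6 (1.62 ± 0.12), Shtn1 (1.57 ± 0.15) and Pilra (1.5 ± 0.16) were also among the 10 largest rises. Nos2 fell from 32.4 ± 9.19 to 7.31 ± 1.05 FPKM (log2 change -1.98 ± 0.22, adjusted p = 0.00196) and the costimulatory gene Cd86 from 24.9 ± 1.56 to 8.93 ± 0.492 FPKM (log2 change -1.38 ± 0.09, adjusted p = 0.000208). Sirpa rose (0.44 ± 0.11) and Cd47 fell (-0.49 ± 0.09), both lost without any 1 library other than PBS 2 (adjusted p up to 0.161 and 0.0842). The cytokine gene Tnf fell from 131 ± 29.4 to 49.5 ± 3.91 FPKM and Arg1 from 46.4 ± 7.93 to 20.6 ± 0.821 FPKM (log2 change -1.12 ± 0.13, adjusted p = 0.00236). Mpo, the myeloperoxidase of primary granules, fell from 189.6 ± 66.3 to 23.7 ± 2.67 FPKM (log2 change -2.90 ± 0.21, adjusted p = 0.000339), Tgm1 from 49.1 ± 6.01 to 9.24 ± 0.121 FPKM, and Ly6d, a marker of lymphoid progenitors, from 16.8 ± 8.69 to 0.157 ± 0.00513 FPKM. Hbb-bs from 126 ± 79.6 to 4.44 ± 0.806 FPKM and Hba-a1 (-4.07 ± 0.43) fell with Ear6 (-2.40 ± 0.25) and Ear1 (-2.46 ± 0.32), whose split between near-identical copies is uncertain. PBS replicate 2 stood apart from the other PBS libraries, at 266 FPKM of Mpo and 218 of Hbb-bs. C1qb (log2 change 2.02 ± 0.37) lost its call without OMV-SIRP 1, OMV-SIRP 2 or OMV-SIRP 3 (adjusted p up to 0.0693) and H2-Eb1 without OMV-SIRP 3 (adjusted p = 0.0513).

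Of the interferon-stimulated list, 18 of 19 members fell (19 adjusted over the list alone, median -1.48, camera adjusted p = 0.000859) in these monocytes. Isg15 fell from 78.2 ± 44.1 to 13.5 ± 1.76 FPKM (log2 change -2.32 ± 0.33, adjusted p = 0.0055), Oasl2 from 23.5 ± 0.809 to 7.75 ± 0.450 FPKM, Ifit1 from 7.66 ± 0.888 to 1.37 ± 0.182 FPKM, and Usp18 (-1.91 ± 0.14) and Rsad2 (-2.15 ± 0.14) fell as well. In the interferon-gamma guanylate-binding list 5 of 9 members fell (7 adjusted over the list alone, median -0.52, camera adjusted p = 0.034). In the cell cycle list 6 of 16 members fell (9 adjusted over the list alone, median -0.33, camera adjusted p = 0.034). Both calls were lost without PBS 1, 2 or 3 or OMV-SIRP 1 or 2 (adjusted p up to 0.0949). Other lists did not pass camera. In the alternative (M2-type) macrophage list 5 of 12 members rose and 2 fell (6 and 2 adjusted over the list alone, median 0.53, camera adjusted p = 0.155 with an estimated correlation). In the proinflammatory (M1-type) list 6 of 13 members fell (7 and 1 adjusted over the list alone, median -0.53, camera adjusted p = 0.179 with an estimated correlation). In the erythroid list 4 of 5 members fell (4 adjusted over the list alone, median -2.78, camera adjusted p = 0.155 with an estimated correlation). In the primary granule list 5 of 10 members fell (7 adjusted over the list alone, median -0.97, camera adjusted p = 0.385 with an estimated correlation). In the B cell list 3 of 5 members fell (3 adjusted over the list alone, median -1.64, camera adjusted p = 0.258 with an estimated correlation). A total of 1026 of 12028 genes tested passed, 369 higher and 657 lower, of which 54 and 159 changed by at least 2-fold. With total-read scaling, which moved the median of all genes to 0.113 on the log2 scale, 675 genes were higher and 406 lower. Of the 20 genes with the largest and smallest changes, 4 (C1qb, H2-Eb1, Hba-a2 and Lpar5) lost their call without at least 1 library. The count was 633, 3563 and 663 without PBS 1, 2 and 3, and 366, 435 and 384 without OMV-SIRP 1, 2 and 3.

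**Figure D2:**
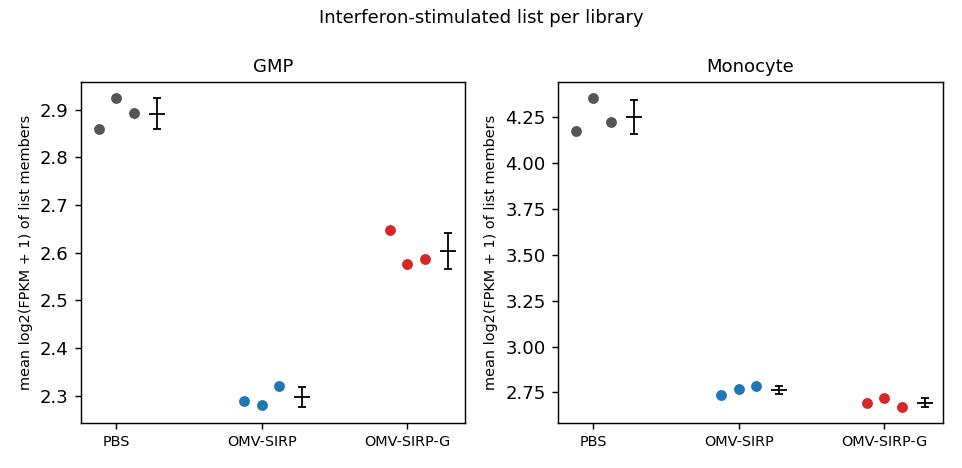
Mean log2(FPKM + 1) over the measured members of the interferon-stimulated list in each GMP and monocyte library (points, 3 per group), with the group mean and SD, on axes that do not start at 0. GMP averaged 2.89 in PBS, 2.3 after OMV-SIRP and 2.6 after OMV-SIRP-G, and monocytes 4.25, 2.76 and 2.69.

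OMV-SIRP-G also lowered interferon-stimulated genes of monocytes, and raised the chemokine gene Ccl5 the most of the genes named. Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) rose from 11.8 ± 5.93 to 325 ± 14.1 FPKM (log2 change 4.77 ± 0.28, adjusted p = 0.000106). Mmp14 rose from 4.30 ± 1.07 to 32.8 ± 2.95 FPKM, the ectoenzyme gene Cd38 from 1.90 ± 0.315 to 9.69 ± 0.111 FPKM, the prostaglandin E synthase gene Ptges from 5.05 ± 0.0707 to 20.3 ± 1.58 FPKM and Il1b from 45.3 ± 13.2 to 150.2 ± 7.61 FPKM. Hspa1b rose from 14.7 ± 1.21 to 50.2 ± 1.61 FPKM, Fos from 205 ± 1.13 to 605 ± 18.4 FPKM and the interleukin 1 receptor antagonist gene Il1rn from 1.30 ± 0.209 to 6.86 ± 0.622 FPKM. Acp5 (1.89 ± 0.21), Shtn1 (1.71 ± 0.15), Pilra (1.62 ± 0.16) and Bcl2a1d (1.57 ± 0.22) were the others of the 10 largest rises. Mpo fell from 189.6 ± 66.3 to 11.7 ± 0.595 FPKM (log2 change -3.85 ± 0.21, adjusted p = 9.69e-05) and the neutrophil elastase gene Elane from 448 ± 236 to 42.7 ± 0.872 FPKM, with the granulocyte progenitor gene Ms4a3 (-2.10 ± 0.26). Hbb-bs from 126 ± 79.6 to 10.01 ± 1.31 FPKM, Hba-a1 (-3.50 ± 0.43) and Hbb-bt (-2.30 ± 0.32) fell, with an uncertain split between copies, as did Ly6d (-3.19 ± 0.31), Nkg7 (-2.32 ± 0.27) and Egr3 (-2.03 ± 0.26). Tnf fell from 131 ± 29.4 to 34.6 ± 3.18 FPKM and Cd86 from 24.9 ± 1.56 to 15.4 ± 0.114 FPKM. Nos2 rose (log2 change 1.04 ± 0.22, adjusted p = 0.0415), lost without any 1 library other than PBS 2 (adjusted p up to 0.17). Arg1, Mrc1 and Sirpa had adjusted p-values of 0.426, 0.439 and 0.185. In the PBS libraries Elane was at 721 FPKM in replicate 2, above the mean of that group.

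In the interferon-stimulated list 17 of 19 members fell (19 adjusted over the list alone, median -1.72, camera adjusted p = 0.000331). Usp18 fell from 17.3 ± 3.49 to 3.17 ± 0.367 FPKM, Mx1 from 16.4 ± 2.38 to 3.58 ± 0.465 FPKM and Xaf1 from 13.7 ± 2.55 to 3.03 ± 0.175 FPKM. The other list calls of this comparison depended on single libraries. In the guanylate-binding list 4 of 9 members fell (6 adjusted over the list alone, median -0.54, camera adjusted p = 0.0206). In the cell cycle list 5 of 16 members fell (9 adjusted over the list alone, median -0.38, camera adjusted p = 0.0206). In the hypoxia and angiogenesis list 3 of 12 members rose (4 adjusted over the list alone, median 0.21, camera adjusted p = 0.0206). Without PBS 3 each of these calls was lost (adjusted p = 0.0508). In the stem and early progenitor list 1 of 8 members fell (6 adjusted over the list alone, median -0.43, camera adjusted p = 0.0293), lost without PBS 1, PBS 2, PBS 3 or OMV-SIRP-G 3 (adjusted p up to 0.159). In the erythroid list 3 of 5 members fell (5 adjusted over the list alone, median -2.30, camera adjusted p = 0.0293), lost without PBS 3 (adjusted p = 0.0734). In the stress list 7 of 14 members rose and 1 fell (7 and 1 adjusted over the list alone, median 0.68, camera adjusted p = 0.032), lost without PBS 1, PBS 2, PBS 3 or OMV-SIRP-G 3 (adjusted p up to 0.117). Primary granule genes did not pass as a list, although 5 of 10 members fell (8 adjusted over the list alone, median -1.20, camera adjusted p = 0.13 with an estimated correlation). In the B cell list 3 of 5 members fell (4 adjusted over the list alone, median -1.57, camera adjusted p = 0.141 with an estimated correlation). A total of 442 genes passed, 184 higher and 258 lower, of which 76 and 114 changed by at least 2-fold. The count was 254, 1479 and 272 without PBS 1, 2 and 3, and 202, 207 and 217 without OMV-SIRP-G 1, 2 and 3.

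Between the treatments, monocytes had more Ccl5, Nos2 and Il1b transcripts and fewer Mrc1 and Mgl2 transcripts after OMV-SIRP-G than after OMV-SIRP. Ccl5 rose from 21.2 ± 3.16 to 325 ± 14.1 FPKM (log2 change 3.89 ± 0.28, adjusted p = 0.000784). Nos2 rose from 7.31 ± 1.05 to 66.0 ± 8.78 FPKM (log2 change 3.01 ± 0.22, adjusted p = 0.000883), Il1b from 31.6 ± 5.04 to 150.2 ± 7.61 FPKM, Arg1 from 20.6 ± 0.821 to 54.9 ± 4.69 FPKM, the haem oxygenase gene Hmox1 (1.51 ± 0.16) and Hspa1a from 10.1 ± 0.567 to 46.3 ± 2.43 FPKM. Mgl2 fell from 32.2 ± 0.574 to 6.97 ± 0.0944 FPKM, Gpnmb from 75.0 ± 1.29 to 22.7 ± 0.646 FPKM and Mrc1 from 5.19 ± 0.512 to 0.532 ± 0.130 FPKM (log2 change -2.01 ± 0.16, adjusted p = 0.00119). The falls of the complement gene C1qb, Clec10a and Tmem176b lost their calls whichever of the 6 libraries was left out (adjusted p up to 0.159, 0.0991 and 0.171). In the hypoxia and angiogenesis list 6 of 12 members rose (10 adjusted over the list alone, median 0.71, camera adjusted p = 0.0068). The proinflammatory list did not pass, although 7 of 13 members rose (7 and 1 adjusted over the list alone, median 0.56, camera adjusted p = 0.17 with an estimated correlation). The interferon-stimulated list had a median log2 change of -0.10 and a camera adjusted p of 0.319. A total of 293 genes passed, 191 higher and 102 lower, and with total-read scaling 142 were higher and 188 lower. The count lay between 59 and 76 without any 1 of the 6 libraries. It was 75 with replicate number as a block, but 2118 in a fit of the 2 compared groups alone. The main fit took its spread partly from the PBS libraries, where replicate 2 stood apart.

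The responses of GMP and monocytes to the same treatment were compared directly, and 2280 of 13337 genes differed for OMV-SIRP and 904 for OMV-SIRP-G. For OMV-SIRP, Arg1 (difference in log2 change -3.0 ± 0.17, adjusted p = 7e-08) and Nos2 (difference in log2 change -3.06 ± 0.24, adjusted p = 1.26e-06) responded lower in monocytes than in GMP, and Mrc1 (difference in log2 change 1.88 ± 0.18, adjusted p = 6.56e-06) higher. The interferon-stimulated list also responded lower in monocytes, where -0.78 was the median difference in log2 change and the camera adjusted p was 0.000255, with 14 of 19 members past the threshold and 16 adjusted over the list alone. For OMV-SIRP-G the corresponding median was -1.24 (camera adjusted p = 3.79e-06), with 14 of 19 members past the threshold and 18 adjusted over the list alone. Hypoxia and angiogenesis genes responded lower in monocytes to OMV-SIRP (9 of 12 lower and 1 higher, the same adjusted over the list alone, median -1.15, camera adjusted p = 0.000426). Cell cycle genes did so for both treatments, with 10 of 16 (13 adjusted over the list alone) past the threshold for OMV-SIRP (median -0.87, camera adjusted p = 0.00204) and 6 (8) for OMV-SIRP-G (median -0.29, camera adjusted p = 0.0151). Dendritic cell genes differed for OMV-SIRP-G (3 of 7 lower, 5 adjusted over the list alone, median -0.66, camera adjusted p = 0.00702). With total-read scaling, which moved the median of all differences to 0.17 on the log2 scale, the OMV-SIRP differences were 1918 higher and 738 lower instead of 912 and 1368. Without monocyte PBS 2 the counts were 3978 and 2027.

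OMV-SIRP libraries of B16 TAM held more MHC class II transcripts than PBS and fewer of T, natural killer and red cells. The cell mix may differ. Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), a scavenger receptor of macrophages, rose from 0.911 ± 0.588 to 13 ± 4.98 FPKM (log2 change 2.85 ± 0.30, adjusted p = 0.00117). The serum amyloid gene Saa3 rose from 0.383 ± 0.370 to 5.35 ± 2.51 FPKM, the protease inhibitor gene Slpi from 1.44 ± 1.04 to 14.7 ± 3.43 FPKM, and the dendritic cell lectin Cd209a from 11.8 ± 1.97 to 34.0 ± 3.29 FPKM. Ifitm1 rose from 28.8 ± 4.77 to 87.6 ± 18.8 FPKM, the kinase gene Fgr from 6.83 ± 0.810 to 18.7 ± 0.997 FPKM, Mgl2 from 14.2 ± 1.65 to 33.2 ± 3.96 FPKM and Spp1 from 144 ± 4.31 to 287 ± 39.4 FPKM. The invariant chain gene Cd74 rose from 2122 ± 268 to 4105 ± 147 FPKM (log2 change 0.96 ± 0.10, adjusted p = 0.00117), with H2-Ab1 (0.94 ± 0.13) and H2-Eb1 (0.92 ± 0.11). The granzyme genes Gzma from 49.1 ± 11.2 to 8.02 ± 0.964 FPKM (log2 change -2.46 ± 0.26, adjusted p = 0.00117) and Gzmb from 65.1 ± 6.21 to 21.8 ± 3.68 FPKM fell, with the perforin gene Prf1 from 30.2 ± 2.22 to 8.39 ± 3.05 FPKM, the checkpoint gene Ctla4 from 31.6 ± 1.01 to 9.65 ± 3.03 FPKM, Gimap4 (-1.96 ± 0.22) and the T cell receptor component Cd3d (-1.41 ± 0.20). The haem synthesis gene Alas2 fell from 200.1 ± 35.4 to 26.0 ± 6.51 FPKM (log2 change -2.91 ± 0.18, adjusted p = 2.2e-05), and Hbb-bs from 7829.6 ± 257 to 1273 ± 152 FPKM (log2 change -2.63 ± 0.10, adjusted p = 7.59e-07). The copies Hba-a1 (-2.79 ± 0.13), Hba-a2 (-2.64 ± 0.21) and Hbb-bt (-2.51 ± 0.31) fell too, with an uncertain split of reads.

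Of the lists, 6 passed camera and none of these calls was lost without any 1 library. In the T and NK cell list 12 of 16 members fell (16 adjusted over the list alone, median -1.42, camera adjusted p = 0.00772). In the erythroid list 5 of 7 members fell (5 adjusted over the list alone, median -2.63, camera adjusted p = 0.00808). In the MHC class II list 8 of 11 members rose (8 adjusted over the list alone, median 0.84, camera adjusted p = 0.0151). In the alternative macrophage list 4 of 15 members rose (6 adjusted over the list alone, median 0.33, camera adjusted p = 0.0151). In the dendritic cell list 2 of 13 members rose (5 adjusted over the list alone, median 0.40, camera adjusted p = 0.0151). In the melanoma list 1 of 11 members fell (5 adjusted over the list alone, median -0.31, camera adjusted p = 0.0151). Mrc1 rose from 26.6 ± 4.34 to 43.5 ± 3.38 FPKM (log2 change 0.70 ± 0.13, adjusted p = 0.0293). This call was lost without PBS 1, 2 or 3 or OMV-SIRP 1 or 2 (up to 0.128). Sirpa, Cd47, Cd86, Arg1 and Nos2 had adjusted p-values of 0.583, 0.962, 0.666, 0.196 and 0.628. A total of 182 of 12542 genes tested passed, 111 higher and 71 lower, of which 61 and 55 changed by at least 2-fold. The count was 100, 84 and 94 without PBS 1, 2 and 3, 73 without OMV-SIRP 1 and 92 without OMV-SIRP 2. Of the 20 genes with the largest and smallest changes, 6 lost their call without at least 1 library.

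OMV-SIRP-G libraries of B16 TAM held more macrophage, phagocytosis and interferon transcripts than PBS, and fewer melanoma, lymphocyte and red cell transcripts. The latter mark other cells, so for both treatments another cell mix and a change within macrophages cannot be told apart. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) rose from 144 ± 4.31 to 916 ± 50.9 FPKM (log2 change 2.66 ± 0.11, adjusted p = 1.69e-06), Saa3 from 0.383 ± 0.370 to 17.5 ± 0.553 FPKM (log2 change 3.78 ± 0.28, adjusted p = 3.24e-05) and Marco from 0.911 ± 0.588 to 22.1 ± 3.48 FPKM. The platelet chemokine gene Ppbp rose from 3.39 ± 1.42 to 42.7 ± 9.93 FPKM, the itaconate synthesis gene Acod1 from 0.716 ± 0.657 to 12.6 ± 1.94 FPKM, and the chitinase-like gene Chil3 from 2.70 ± 1.51 to 26.3 ± 4.19 FPKM. Slfn4 rose from 2.63 ± 0.707 to 28.6 ± 4.18 FPKM, Ms4a4a from 20.2 ± 5.89 to 135 ± 8.80 FPKM, the coagulation factor gene F13a1 from 6.09 ± 1.20 to 43.2 ± 2.07 FPKM and the lysozyme gene Lyz1 (2.55 ± 0.30). Mrc1 rose from 26.6 ± 4.34 to 127 ± 7.31 FPKM (log2 change 2.23 ± 0.13, adjusted p = 7.77e-06) and Arg1 from 37.3 ± 6.52 to 153 ± 18.8 FPKM (log2 change 2.01 ± 0.17, adjusted p = 6.23e-05). Nos2 rose from 2.30 ± 0.705 to 7.75 ± 2.65 FPKM (log2 change 1.38 ± 0.29, adjusted p = 0.0102) and Sirpa from 89.3 ± 11.5 to 203 ± 9.20 FPKM (log2 change 1.18 ± 0.11, adjusted p = 0.000101). Cd47 rose (0.65 ± 0.16), lost without PBS 1, PBS 3, OMV-SIRP-G 1 or OMV-SIRP-G 3 (adjusted p up to 0.0687). The melanosome gene Pmel fell from 1416 ± 148 to 358 ± 36.1 FPKM (log2 change -1.98 ± 0.11, adjusted p = 5.37e-06) and the tyrosinase gene Tyr from 42.5 ± 3.74 to 15.9 ± 0.852 FPKM. Gzma fell from 49.1 ± 11.2 to 6.94 ± 3.11 FPKM. The 10 largest falls were of Ctrb1, Prss2, Try4, Clps, Cela2a, Amy2a1 and Cpa1, which encode secreted pancreatic proteins, and Alb, Apoa2 and Serpina3k, known from liver. Ctrb1 fell from 191 ± 119.7 to 0.810 ± 1.40 FPKM (log2 change -6.78 ± 1.05, adjusted p = 0.00458), and Cpa1, Clps and Cela2a were listed at 0 in all 3 OMV-SIRP-G libraries against 20.3 ± 12.3, 27.6 ± 16.3 and 25.5 ± 19.4 FPKM in PBS. The albumin gene Alb fell from 252 ± 114 to 18.1 ± 30.7 FPKM (adjusted p = 0.0446). Its call and Apoa2's were lost without PBS 1, 2 or 3 or OMV-SIRP-G 1 or 2 (adjusted p up to 0.14 and 0.139). Amy2a1 lost its call without PBS 1 or 3 or OMV-SIRP-G 1, 2 or 3 (up to 0.123). Prss2 lost it without PBS 2 or OMV-SIRP-G 2 (up to 0.0534).

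Of the lists, 11 passed camera. In the macrophage identity list 11 of 12 members rose (11 adjusted over the list alone, median 1.36, camera adjusted p = 0.00844). In the phagocytosis and scavenging list 11 of 15 members rose (13 adjusted over the list alone, median 1.17, camera adjusted p = 0.00283). In the monocyte lineage list 9 of 14 members rose (10 and 1 adjusted over the list alone, median 1.05, camera adjusted p = 0.00844). In the interferon-stimulated list 13 of 20 members rose (14 adjusted over the list alone, median 0.65, camera adjusted p = 0.00844), with Oas2 (1.04 ± 0.17) and Oasl2 (1.02 ± 0.15) higher. In the TLR and NF-kB response list 8 of 19 members rose (10 and 1 adjusted over the list alone, median 0.52, camera adjusted p = 0.017). In the immune checkpoint and CD47-SIRPA list 5 of 11 members rose (6 adjusted over the list alone, median 0.64, camera adjusted p = 0.018), with the inhibitory receptor genes Lilrb4a (2.03 ± 0.30) and Pirb (1.29 ± 0.12) higher. In the melanoma list 11 of 11 members fell (11 adjusted over the list alone, median -1.74, camera adjusted p = 0.00283). In the T and NK cell list 15 of 16 members fell (16 adjusted over the list alone, median -1.39, camera adjusted p = 0.0124). In the erythroid list 5 of 7 members fell (6 adjusted over the list alone, median -2.40, camera adjusted p = 0.0175). In the alternative macrophage list 6 of 15 members rose and 1 fell (9 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 0.0203), a call lost without OMV-SIRP-G 2 or OMV-SIRP-G 3 (adjusted p up to 0.0701). In the hypoxia and angiogenesis list 7 of 13 members rose and 1 fell (7 and 1 adjusted over the list alone, median 0.40, camera adjusted p = 0.0365), a call lost without PBS 1, OMV-SIRP-G 2 or OMV-SIRP-G 3 (adjusted p up to 0.0713). A total of 1895 genes passed, 982 higher and 913 lower, of which 309 and 574 changed by at least 2-fold. The count was 1192 without PBS 2 and 1177 without PBS 3.

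Compared with OMV-SIRP, OMV-SIRP-G libraries of B16 TAM held more macrophage and monocyte transcripts and fewer melanoma and dendritic cell transcripts. Whether the mix of cells or the macrophages themselves changed was not tested. The matricellular gene Thbs1 rose from 15.5 ± 3.49 to 93.0 ± 2.79 FPKM (log2 change 2.53 ± 0.16, adjusted p = 3.52e-05), the monocyte surface gene Ly6c2 from 2.93 ± 0.742 to 15.2 ± 1.49 FPKM, and Chil3 (2.62 ± 0.25), Cxcl3 (2.37 ± 0.22) and Slfn4 (2.37 ± 0.24) were the other large rises. Mrc1 (1.53 ± 0.13), Arg1 (1.42 ± 0.17), Nos2 (1.92 ± 0.29) and Sirpa (0.95 ± 0.11) also rose. The Fc receptor gene Fcgr1 rose from 44.8 ± 8.36 to 127 ± 6.75 FPKM, the colony-stimulating factor receptor gene Csf1r from 77.2 ± 5.02 to 155 ± 2.03 FPKM and the integrin gene Itgam (1.24 ± 0.12). Cd209a fell from 34.0 ± 3.29 to 10.7 ± 1.53 FPKM and Flt3 fell as well (-1.08 ± 0.17). The pancreas genes Ctrb1, Cela2a, Prss2, Clps and Try4 made up the 5 largest falls, and Try4 lost its call without OMV-SIRP-G 1 or OMV-SIRP-G 2 (adjusted p up to 0.0543). In the phagocytosis list 13 of 15 members rose (14 adjusted over the list alone, median 1.09, camera adjusted p = 0.00218). In the macrophage identity list 11 of 12 members rose (11 adjusted over the list alone, median 1.21, camera adjusted p = 0.00828). In the monocyte lineage list 8 of 14 members rose (10 and 1 adjusted over the list alone, median 0.80, camera adjusted p = 0.00828). In the interferon-stimulated list 11 of 20 members rose (15 adjusted over the list alone, median 0.63, camera adjusted p = 0.00828). In the TLR and NF-kB list 10 of 19 members rose and 1 fell (11 and 1 adjusted over the list alone, median 0.59, camera adjusted p = 0.00828). In the hypoxia list 7 of 13 members rose (8 adjusted over the list alone, median 0.56, camera adjusted p = 0.0102). In the checkpoint list 7 of 11 members rose and 1 fell (8 and 1 adjusted over the list alone, median 0.62, camera adjusted p = 0.0231). In the melanoma list 11 of 11 members fell (11 adjusted over the list alone, median -1.43, camera adjusted p = 0.00218). In the dendritic cell list 8 of 13 members fell (9 and 1 adjusted over the list alone, median -0.95, camera adjusted p = 0.00828). In the cholesterol synthesis list 7 of 14 members fell (8 adjusted over the list alone, median -0.53, camera adjusted p = 0.0188). In the stress list 8 of 14 members rose (9 adjusted over the list alone, median 0.54, camera adjusted p = 0.0263), a call lost without OMV-SIRP-G 1, OMV-SIRP-G 2 or OMV-SIRP-G 3 (adjusted p up to 0.0744). The T and NK cell list had a median log2 change of -0.07 and a camera adjusted p of 0.955. A total of 1502 genes passed, 797 higher and 705 lower.

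**Figure D3:**
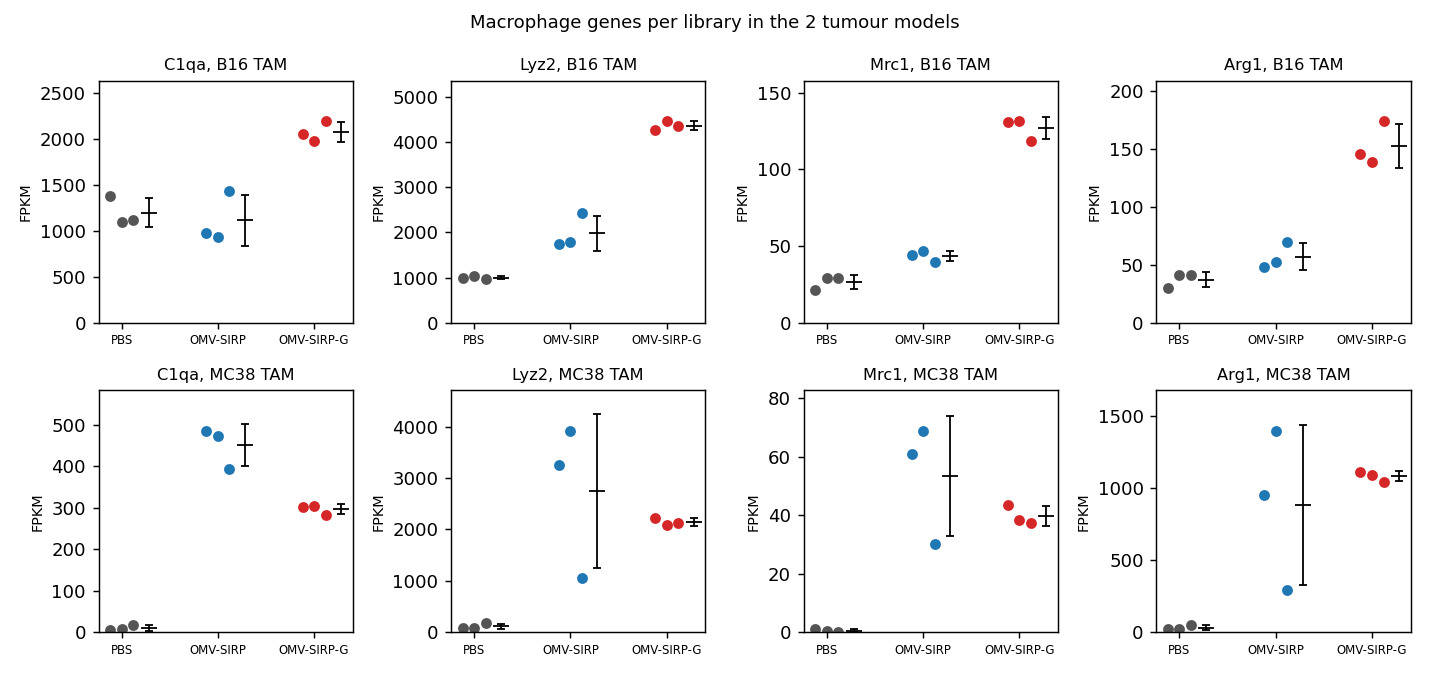
FPKM of C1qa, Lyz2, Mrc1 and Arg1 in each library (points, 3 per group) of B16 TAM (top) and MC38 TAM (bottom), with the group mean and SD, on linear axes from 0 that differ between panels. Mrc1 averaged 26.6 in PBS and 127 after OMV-SIRP-G in B16 TAM, and 0.553 in PBS, 53.3 after OMV-SIRP and 39.7 after OMV-SIRP-G in MC38 TAM.

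In TAM of MC38 tumours the PBS libraries held few transcripts of macrophages, and OMV-SIRP libraries held many. C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), a complement component made by macrophages, rose from 9.52 ± 6.78 to 451 ± 50.8 FPKM (log2 change 5.61 ± 0.36, adjusted p = 0.000149). C1qb rose from 19.1 ± 12.9 to 523 ± 148 FPKM, C1qc from 6.54 ± 3.22 to 198 ± 23.5 FPKM, Chil3 from 6.18 ± 2.38 to 299.8 ± 137 FPKM, Mrc1 from 0.553 ± 0.581 to 53.3 ± 20.5 FPKM (log2 change 5.11 ± 0.34, adjusted p = 0.000183) and Arg1 from 30.8 ± 19.2 to 882 ± 556 FPKM (log2 change 4.69 ± 0.55, adjusted p = 0.0016). The MHC class II gene H2-Eb1 rose from 20.6 ± 10.5 to 571 ± 239 FPKM, H2-Ab1 (4.58 ± 0.41), Cd74 (3.74 ± 0.33), the lysozyme gene Lyz2 (4.48 ± 0.47), the Fc receptor gene Fcgr3 (4.20 ± 0.53) and Csf1r from 6.71 ± 1.60 to 78.8 ± 33.6 FPKM. Pld4 (4.86 ± 0.49) and Retnlg (4.77 ± 0.72) rose as well, and Retnla was listed at 0 in the PBS libraries against 54.3 ± 52.1 after OMV-SIRP. Sirpa rose from 15.2 ± 6.26 to 66.9 ± 27.1 FPKM (log2 change 2.06 ± 0.33, adjusted p = 0.00672). The neutrophil genes S100a8 from 162 ± 60.3 to 3.89 ± 3.70 FPKM (log2 change -5.46 ± 0.68, adjusted p = 0.00212), S100a9 from 207 ± 90.8 to 7.52 ± 5.80 FPKM and Lcn2 from 65.3 ± 26.4 to 4.41 ± 5.87 FPKM fell, with the prostaglandin synthase gene Ptgs2 from 257 ± 53.8 to 50.6 ± 49.7 FPKM and the cytokine gene Il6 from 26.2 ± 7.43 to 3.80 ± 3.85 FPKM. Of the 20 genes with the largest and smallest changes, 5 (Serpinb2, Prl2c2, Il10, Rnd1 and Ngp) lost their call without at least 1 library. Cd47, Cd86 and Nos2 had adjusted p-values of 0.223, 0.451 and 0.216.

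No list passed camera with an estimated correlation, although many had most members past the threshold. In the macrophage identity list 10 of 12 members rose (11 and 1 adjusted over the list alone, median 3.09, camera adjusted p = 0.0935). In the MHC class II list 9 of 11 members rose (11 adjusted over the list alone, median 3.31, camera adjusted p = 0.0935). In the alternative macrophage list 11 of 14 members rose and 1 fell (12 and 1 adjusted over the list alone, median 2.96, camera adjusted p = 0.0654). In the phagocytosis list 12 of 14 members rose (13 adjusted over the list alone, median 2.79, camera adjusted p = 0.0935). In the lipid-associated TAM list 12 of 15 members rose (12 and 2 adjusted over the list alone, median 1.90, camera adjusted p = 0.0654). In the monocyte lineage list 10 of 14 members rose (11 adjusted over the list alone, median 2.46, camera adjusted p = 0.0935). In the glycolysis list 12 of 14 members rose (14 adjusted over the list alone, median 1.14, camera adjusted p = 0.0935). In the neutrophil maturation list 4 of 8 members fell and 1 rose (4 and 1 adjusted over the list alone, median -0.84, camera adjusted p = 0.314). In the T and NK cell list 3 of 16 members rose (5 adjusted over the list alone, median 0.55, camera adjusted p = 0.314). In the mitochondrially encoded list 13 of 13 members rose (13 adjusted over the list alone, median 2.43, camera adjusted p = 0.0935), and mitochondrial messenger RNA took 18.1% ± 3.35 of reads (SD, n = 3) after OMV-SIRP and 3.03% ± 0.776 in PBS. A total of 1534 of 14089 genes tested passed, 1042 higher and 492 lower, of which 847 and 289 changed by at least 2-fold. With total-read scaling, which moved the median of all genes to -0.267 on the log2 scale, 697 were higher and 1635 lower. The count was 829 without PBS 1 and 728 without OMV-SIRP 1.

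OMV-SIRP-G libraries of MC38 TAM also held more macrophage transcripts than PBS, and more transcripts of several T and NK cell and dendritic cell genes. Arg1 rose from 30.8 ± 19.2 to 1085 ± 36.3 FPKM (log2 change 5.25 ± 0.55, adjusted p = 0.000631), C1qa from 9.52 ± 6.78 to 297 ± 11.8 FPKM, Mrc1 from 0.553 ± 0.581 to 39.7 ± 3.35 FPKM, and Chil3 (5.41 ± 0.37). The integrin gene Itgax rose from 0.337 ± 0.306 to 39.3 ± 2.51 FPKM, H2-Aa from 11.7 ± 3.53 to 341 ± 11.6 FPKM, H2-Eb1 (4.91 ± 0.37) and H2-Ab1 (4.86 ± 0.41). Gzma rose from 10.7 ± 9.79 to 360.1 ± 26.6 FPKM (log2 change 5.78 ± 1.12, adjusted p = 0.00829), Gzmb from 31.1 ± 1.61 to 215 ± 12.8 FPKM, the interleukin 12 subunit gene Il12b (4.33 ± 0.53) and the dendritic cell gene Fscn1 from 49.5 ± 12.4 to 391 ± 11.8 FPKM. The proteasome subunit gene Psmb8 rose (2.05 ± 0.18) and the peptide transporter gene Tap2 (1.64 ± 0.21). Scimp was listed at 0 in the PBS libraries. Sirpa rose from 15.2 ± 6.26 to 73.0 ± 5.03 FPKM, Cd86 from 15.8 ± 2.44 to 55.4 ± 4.88 FPKM (log2 change 1.75 ± 0.32, adjusted p = 0.00663), and Cd47 (0.78 ± 0.15). Nos2 rose (log2 change 1.97 ± 0.59, adjusted p = 0.0447), a call lost without any of the 6 libraries (adjusted p up to 0.128). The neutrophil genes S100a9 from 207 ± 90.8 to 6.94 ± 4.42 FPKM, S100a8 from 162 ± 60.3 to 7.94 ± 2.41 FPKM, Lcn2 from 65.3 ± 26.4 to 1.62 ± 0.695 FPKM and Ngp (-3.56 ± 0.61) fell, with the cystathionase gene Cth (-2.72 ± 0.51), the amino acid transporter gene Slc1a4 (-2.32 ± 0.30), Slc43a3 (-2.30 ± 0.20), 3830403N18Rik (-2.71 ± 0.30) and Top2a (-1.20 ± 0.17).

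No list passed camera with an estimated correlation here either. In the macrophage identity list 11 of 12 members rose (11 and 1 adjusted over the list alone, median 3.08, camera adjusted p = 0.125). In the MHC class II list 11 of 11 members rose (11 adjusted over the list alone, median 3.34, camera adjusted p = 0.125). In the MHC class I list 11 of 13 members rose (11 adjusted over the list alone, median 1.16, camera adjusted p = 0.125). In the phagocytosis list 13 of 14 members rose and 1 fell (13 and 1 adjusted over the list alone, median 2.87, camera adjusted p = 0.125). In the alternative macrophage list 12 of 14 members rose (12 adjusted over the list alone, median 3.09, camera adjusted p = 0.0648). In the proinflammatory list 9 of 16 members rose (9 adjusted over the list alone, median 1.55, camera adjusted p = 0.277). In the lipid-associated TAM list 12 of 15 members rose (13 and 1 adjusted over the list alone, median 1.78, camera adjusted p = 0.0648). In the T and NK cell list 11 of 16 members rose (13 adjusted over the list alone, median 1.53, camera adjusted p = 0.125). In the dendritic cell list 6 of 10 members rose and 1 fell (8 and 1 adjusted over the list alone, median 1.88, camera adjusted p = 0.215). In the checkpoint list 10 of 12 members rose (10 adjusted over the list alone, median 1.88, camera adjusted p = 0.125). In the stress list 10 of 14 members rose (13 adjusted over the list alone, median 1.94, camera adjusted p = 0.0648). In the cell cycle list 4 of 16 members fell (6 adjusted over the list alone, median -0.44, camera adjusted p = 0.242). Mitochondrial messenger RNA took 5.78% ± 0.197 of reads (SD, n = 3). A total of 2809 genes passed, 1843 higher and 966 lower, of which 1518 and 567 changed by at least 2-fold. With total-read scaling 1551 were higher and 1431 lower. Of the 20 genes with the largest and smallest changes, 2 (Fam171b and Morn2) lost their call without at least 1 library. The count was 1262, 1339 and 1304 without OMV-SIRP-G 1, 2 and 3.

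Between OMV-SIRP-G and OMV-SIRP 54 genes of MC38 TAM passed the threshold, 21 higher and 33 lower, and all 10 genes named by size lost their call without at least 1 library. The milk fat globule gene Mfge8 was higher (19.7 ± 8.88 to 78.8 ± 5.07 FPKM, adjusted p = 0.0427). So were Fscn1 (118 ± 57.3 to 391 ± 11.8 FPKM) and the transcription factor gene Irf1 (20.7 ± 5.23 to 58.6 ± 3.26 FPKM). The receptor ligand gene Gas6 was lower (17.0 ± 4.61 to 2.0 ± 0.897 FPKM, adjusted p = 0.0199). Mfge8, Irf1 and Gas6 lost their calls without OMV-SIRP 1 or OMV-SIRP-G 1, 2 or 3 (adjusted p up to 0.284, 0.248 and 0.213). Fscn1 lost its call without any of these or OMV-SIRP 2 (up to 0.288). Also lower was mt-Co1 (81947 ± 18817 to 21915 ± 751 FPKM, adjusted p = 0.00899), lost without OMV-SIRP-G 1, OMV-SIRP-G 2 or OMV-SIRP-G 3 (adjusted p up to 0.14). In the mitochondrially encoded list 7 of 13 members fell (13 adjusted over the list alone, median -1.69, camera adjusted p = 0.112 with an estimated correlation). In all, 1675 genes had an unadjusted p under 0.05. With total-read scaling, which moved the median of all genes to 0.207, 28 were higher and 20 lower, and limma voom called 49 higher and 44 lower. The count was 11, 162 and 189 without OMV-SIRP 1, 2 and 3, and 0 without OMV-SIRP-G 1, 2 or 3.

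**Figure D4:**
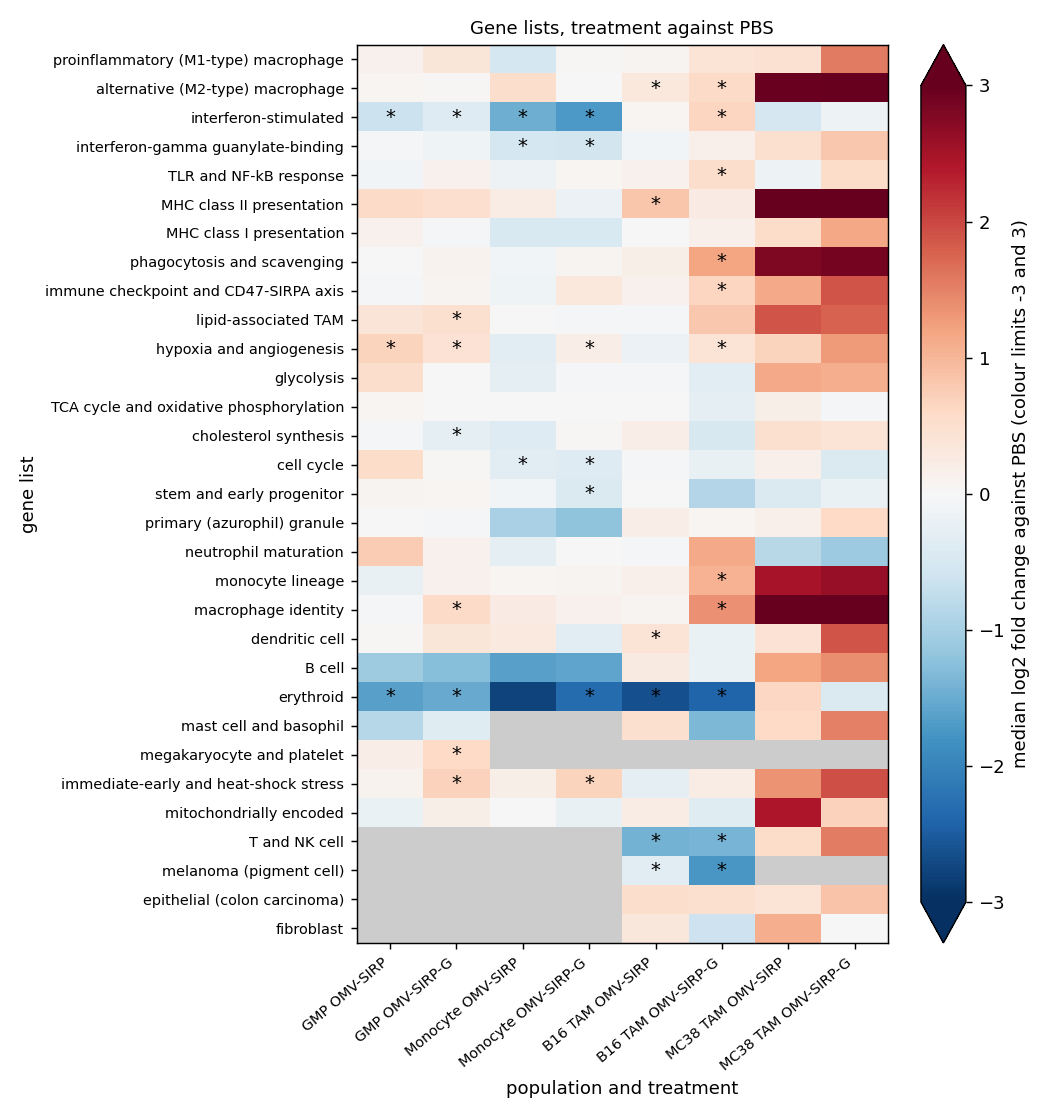
Median log2 change of each gene list (vertical) in each treatment against PBS (horizontal), coloured from -3 to 3, with an asterisk where camera with an estimated correlation gave an adjusted p under 0.05 and grey where fewer than 5 members were measured. The interferon-stimulated list was lower in GMP and monocytes (median -1.72 in monocytes after OMV-SIRP-G) and higher in B16 TAM after OMV-SIRP-G (median 0.65).

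The calls of the 2 treatments against PBS overlapped in every population. In GMP 435 genes were higher and 305 lower under both, where independent lists would share 88.4 and 48.2. In monocytes the shared counts were 97 and 192 (5.65 and 14.1 for independent lists), in B16 TAM 60 and 57 (8.69 and 5.17), and in MC38 TAM 839 and 376 (136 and 33.7). Both comparisons used the same PBS libraries. Simulated unchanged groups shared 0 to 0.02 genes on average, but such groups give few calls, so this cannot size what shared PBS libraries add. The log2 changes of the treatments correlated across genes, which are not independent replicates, at 0.567, 0.698, 0.44 and 0.814 in these 4 populations, against 0.5, 0.501, 0.5 and 0.501 in the simulations. In the same order the covariances were 0.0481, 0.113, 0.129 and 0.74, against 0.0107, 0.0287, 0.0528 and 0.11 in the simulations. The 3 PBS libraries are too few to be split between the treatments, so part of the excess may come from them.

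The tumour models were scaled separately and were set side by side without a test. Among 11380 genes measured in both, the log2 changes correlated across genes at 0.0818 (Spearman 0.0501) for OMV-SIRP and 0.214 (Spearman 0.21) for OMV-SIRP-G. For OMV-SIRP 53 genes were higher in both models and 1 lower, where independent lists would share 7.5 and 2.24. For OMV-SIRP-G the shared counts were 468 and 87, against 144 and 49.7. Of the genes lower in B16 TAM, 15 of 64 were higher in MC38 TAM for OMV-SIRP and 141 of 686 for OMV-SIRP-G, where independent lists would give 5.58 and 102.7. Of those higher in B16 TAM, 1 of 86 and 20 of 962 were lower in MC38 TAM, against 3.02 and 69.7. Whether a gene's response differed between the models was not tested.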

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

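Tests of the 3 patterns weighed here were chosen after the result was seen; the tests of other splits of the libraries were fixed before their results were seen.

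The responses of GMP and monocytes to the same treatment differed, by a test of the difference itself, in 2280 genes for OMV-SIRP and 904 for OMV-SIRP-G. Of 100 splits of the libraries drawn, 1, the real one, gave as many genes for each treatment, and the highest of the others gave 1302 and 371. The splits exchanged libraries between treatment and PBS within each population, so they compare with no treatment effect and not with equal effects. They cannot exclude chance differences between mice either, because the libraries of a group may not come from separate mice. For OMV-SIRP the change was higher in monocytes for Tlr9 (difference in log2 change 1.83), Fos (1.72), Lpar5 (1.65), Saa3 (1.65) and Mmp14 (1.47). It was lower in monocytes for Nos2 (-3.06), Arg1 (-3.0), Mpo (-2.84), Retnlg (-2.82) and Slfn1 (-2.53). For OMV-SIRP-G it was higher for Ccl5 (3.25), Saa3 (2.18), Ptges (1.63), Pilrb1 (1.48) and Smpdl3b (1.45), and lower for Mpo (-3.86), Elane (-3.38), Slfn1 (-2.93), Retnlg (-2.85) and Gpnmb (-2.81). Tlr9 lost its call without GMP PBS 1 or monocyte OMV-SIRP 3 (adjusted p up to 0.0525). Saa3 lost its call for OMV-SIRP without any 1 library other than GMP PBS 1 and monocyte PBS 2 (up to 0.11), and for OMV-SIRP-G without GMP PBS 2 or 3, GMP OMV-SIRP-G 1, 2 or 3, or monocyte OMV-SIRP-G 1 or 3 (up to 0.0642).

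Interferon-stimulated genes were lower in monocytes of both treated groups than in PBS. One PBS library, replicate 2, stood apart in other genes, but without it the weaker of the list medians was still -1.47. With total-read scaling in place of the authors' scaling the weaker median was -1.31. Neither value leaves room for that library or the scaling as the whole cause. The treatments and another cell mix in PBS stay open and were not tested.

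Macrophage genes were higher in both treated groups of MC38 TAM than in PBS. If other cells had diluted all leukocytes alike in the PBS libraries, the macrophage identity and pan-leukocyte medians would match. The macrophage median was higher by at least 1.24, just beyond the spread of 1.2 among its members. The pan-leukocyte median was itself 1.45 (OMV-SIRP) and 1.84 (OMV-SIRP-G), so dilution may be part of the change. The lower of the macrophage medians was 2.87 with total-read scaling, so the scaling is not the whole cause. A lower share of macrophages in the PBS libraries would raise the genes of other cell types alike. The gap between the neutrophil and the T and NK cell medians was -1.39, within the spread of 3.2 among neutrophil genes, so a different mix of cells and a change within macrophages cannot be told apart.

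Genes of pancreas and liver were lower in B16 TAM after OMV-SIRP-G than after PBS. Of further pancreas genes not seen before, 85.7% (6 of 7) reached an FPKM of 1 in PBS, as did 6 of 7 in OMV-SIRP and 3 in OMV-SIRP-G. Of further liver genes, 100% (11 of 11) reached it in PBS, with Apoa1 at 74.9, Hp at 41.6 and Ahsg at 28.8, against 7 of 11 in OMV-SIRP-G. Both values are what RNA of these organs in the PBS and OMV-SIRP libraries would give. At which step such RNA could have entered was not tested. The OMV-SIRP-G libraries were not free of these transcripts, with the pancreas gene Cela1 at 14.6 against 23.4 in PBS. The pancreas gene Zg16 went the other way, at 5.14 in PBS and 23.5 in OMV-SIRP-G.

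For each of the other 12 comparisons the real split, 1 of the 10 possible, gave the most genes, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 2232 and 1, 1471 and 1, and 1821 and 0 in GMP. They were 1026 and 1, 442 and 1, and 293 and 0 in monocytes. In B16 TAM they were 182 and 6, 1895 and 2, and 1502 and 6. In MC38 TAM they were 1534 and 2, 2809 and 1, and 54 and 2.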

How the results depend on the processing

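Total-read scaling, limma voom and the joint leave-out of 2 MC38 TAM libraries were tests chosen after the results were seen, and all other alternatives were planned. Of 25281 recomputed values of named genes, 23144 stayed on their side of the threshold, 1701 were no longer past it, 434 were newly past it and 2 turned direction while past it in either setting. For gene lists these numbers were 5210, 160, 398 and 0 of 5768. Among the values that stayed on their side, 124 of genes and 210 of lists changed sign while past the threshold in neither setting. Counts of genes called stayed within 1.5 times the reported count in 133 of 209 cases.

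Libraries were left out in turn, which leaves a group with 2 libraries. In GMP the counts of genes called then lay between 1390 and 2144 (OMV-SIRP against PBS), 892 and 1882 (OMV-SIRP-G against PBS), and 1068 and 1333 (OMV-SIRP-G against OMV-SIRP). In monocytes, in the same order, they lay between 366 and 3563, 202 and 1479, and 59 and 76. In B16 TAM they lay between 73 and 144, 1177 and 1470, and 1005 and 1327, and in MC38 TAM between 728 and 2002, 1262 and 2679, and 0 and 189. The differences between GMP and monocytes lay between 1735 and 3978 for OMV-SIRP and between 621 and 2027 for OMV-SIRP-G.

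A minimum log2 change of 1, which by construction keeps fewer genes, left 114, 137 and 61 genes in GMP, 213, 190 and 81 in monocytes, 116, 883 and 631 in B16 TAM, and 492 and 252 differences between GMP and monocytes. Without the filter on low values, where more genes are tested, 154 genes passed between the treatments in monocytes, 112 for OMV-SIRP and 925 between the treatments in B16 TAM, and 762, 1725 and 16 in MC38 TAM. Fits of the 2 compared groups alone gave 284, 177 and 2118 genes in monocytes and 409 for OMV-SIRP in MC38 TAM. For MC38 TAM, total-read scaling gave 2332 genes for OMV-SIRP and limma voom 93 between the treatments. PBS 3 and OMV-SIRP 2 of MC38 TAM had the fewest genes with a read. Without both, 4701 genes passed for OMV-SIRP-G against PBS and 644 between the treatments. The causes of these shifts were not tested.

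With replicate number as a block the counts were 520, 242 and 75 in monocytes and 8 between the treatments in MC38 TAM, and no other count moved by more than 1.5 times. Of 70 camera calls of gene lists, 42 were no longer past the threshold with the block, and the cause was not tested. The Results mark list calls only for losses without single libraries. Deviations of same-numbered libraries correlated between -0.02 and 0.223 in GMP, -0.37 and 0.25 in monocytes, 0.000101 and 0.0779 in B16 TAM, and -0.0343 and 0.0534 in MC38 TAM, with 3, 2, 0 and 0 of 9 pairs over 0.1. The numbers were thus not taken to pair the libraries.

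Of the 2 values that turned direction, Cd79b in monocytes after OMV-SIRP ranged from -0.34 without PBS 1 to 0.29 without PBS 2 when libraries were left out. With limma voom the difference between GMP and monocytes was -0.11 for Gzmb under OMV-SIRP, and the cause was not tested. Of 70 calls of gene lists, 0 changed sign with total-read scaling, but 16 were no longer past the threshold, as were 26 in fits of the 2 compared groups alone and 6 with median-of-ratios scaling. Depth limited genes with low FPKM, whose log2 changes the pseudocount of 1 shrinks.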

Other observations

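The tests in this part were fixed before the data were examined, and 0 were added, although the genes and lists to describe were picked after their values were seen.

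Some fibroblast genes changed in the tumour models, without the list passing camera. In MC38 TAM after OMV-SIRP, 4 of 9 members, all collagen genes, were higher than in PBS (5 adjusted over the list alone, median 1.10, limma camera adjusted p = 0.179 with an estimated correlation). Col1a2 rose from 0.874 ± 0.439 to 12.4 ± 3.87 FPKM (adjusted p = 0.000911) and Col1a1 from 1.45 ± 0.672 to 7.60 ± 1.61 FPKM (adjusted p = 0.00865), and both calls held without each library in turn. Col3a1 lost its call without PBS 1, PBS 2 or OMV-SIRP 1 (adjusted p up to 0.069), and Col5a1 without PBS 1, PBS 2, OMV-SIRP 1 or OMV-SIRP 3 (up to 0.0963). After OMV-SIRP-G, 2 members were higher than in PBS and 1 lower (2 and 2 adjusted over the list alone, median -0.01, camera adjusted p = 0.954), and Dcn fell from 8.33 ± 2.15 to 2.57 ± 0.478 FPKM (adjusted p = 0.0153), a call lost without OMV-SIRP-G 1 or 3 (up to 0.0618). Against OMV-SIRP the median was -1.06. In B16 TAM 4 of 7 members were lower after OMV-SIRP-G than after OMV-SIRP (6 adjusted over the list alone, median -1.08, camera adjusted p = 0.0711).

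Cdh1, which encodes E-cadherin and was listed here as an epithelial gene, moved in opposite directions in progenitors and in MC38 TAM. In GMP it fell from 12.4 ± 0.104 to 5.03 ± 0.361 FPKM after OMV-SIRP and to 7.17 ± 0.0773 FPKM after OMV-SIRP-G. In MC38 TAM it rose from 1.14 ± 0.989 to 14.2 ± 4.85 and 28.2 ± 1.73 FPKM. These 4 calls held without each library in turn. In B16 TAM it was higher as well (log2 change 0.91 and 0.64, adjusted p = 0.0293 and 0.0334), calls lost in 6 and 5 of 6 leave-outs (adjusted p up to 0.162 and 0.132). GMP and MC38 TAM lie in separately scaled tables, so the difference between them was not tested. Cdh1 was the 1 of 5 measured epithelial members past the threshold in each MC38 TAM comparison with PBS (camera adjusted p = 0.259 and 0.252).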
